A study of Mus musculus with 4 samples.

How the data were processed

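Gene expression was measured on 4 arrays with RNA from cerebella dissected on the day of birth (postnatal day 0) from C57Bl/6 mice. Per the labels, every array compared RNA of mice with a conditional knockout of Smarca5 (cKO), the gene of the ISWI chromatin remodelling ATPase Snf2h, directly with RNA of wild-type mice. Total RNA was isolated with Trizol, and labelled cDNA was made with a dendrimer kit from Genisphere. The cKO RNA carried Cy5 on replicates 1 and 3 and Cy3 on replicates 2 and 4. The labels name 3 RNA samples per genotype. Replicates 3 and 4 used the same cKO sample, and replicates 1 and 4 the same wild-type sample. Nothing in the labels says whether an RNA sample came from 1 animal or a pool. The number of arrays limits the precision of every value.

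The authors deposited 1 log ratio per feature and array, which was read as a log2 ratio. Scanner intensities were not used here, so no filter on dim features was possible. The steps by which the authors normalized the arrays are not given in the sources used here. Each deposited column had a mean of about 0, and the deposited medians were 0.01, 0, 0.01 and -0.02 on replicates 1 to 4. The log base of the deposited ratios is not stated. Base 10 was ruled out because the largest ratio, of size -10.27, would exceed the range of scanner intensities. A natural log was not ruled out, in which case every fold given here would be too small.

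The direction of the deposited ratios was settled in part. A rule fixed before the data were examined said that the columns of the dye-flip arrays were to be turned if arrays of opposite dye correlated below 0. That median correlation was -0.171 over features and -0.03 over genes, so the rule would have turned them. It was set aside after the values were seen. The reason was a set of 48 features, repeated at a fixed step of the feature numbers, that carried signal of 1 dye. Their median ratio was -7.03 and -6.38 on the arrays with cKO in Cy5, and 7.04 and 6.61 on the arrays with cKO in Cy3. Ratios of 1 fixed dye over the other would not change sign in this way, so the columns were taken to be already 1 genotype over the other. The direction cKO over wild type is likely, because the labels place cKO in channel 2 on every array. The feature named Smarca5 also lay below 0 on all 4 arrays, which was used to choose this direction. Another feature, whose clone name is now a synonym of Smarca5, lay above 0 on all 4 arrays. The turned columns were kept as an alternative.

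The platform annotation gave 1 gene symbol to 30457 of the 38880 features and none to 8423, and no feature had several. Of the 21476 symbols, 12795 were current names in RefSeq for GRCm38.p6, which was used for names only. Another 8317 were replaced through a synonym that pointed to 1 gene, and 364 were kept as given. Values were centred on each array's median, and features of a symbol were averaged, which left 21476 genes.

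Genes were fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with the data.table package (version 1.17.8). The model had an intercept alone, so that a ratio of 0 was the null value. Arrays that shared an RNA sample were given a correlation of 0.5, which is what sharing 1 of 2 RNA samples gives when all spread lies between samples. With this correlation the estimate is the mean of replicates 1 to 3, and replicate 4 has a weight of 0 in the estimate but still enters the residual variance. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The p-values rest on 3 RNA samples per genotype, and the spread they measure mixes that between samples with that between arrays. Arrays sharing an RNA sample correlated across genes at 0.007 (replicates 1 and 4) and -0.053 (replicates 3 and 4), where the fit assumed 0.5.

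A total of 31 gene lists, fixed before the data were examined, were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. They covered cerebellar and other cell types, proliferation, cell death, chromatin, stress and metabolism. Camera with an estimated inter-gene correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. A camera p at the preset correlation sets a list's genes against the other genes and does not measure the spread between RNA samples. The named genes followed a fixed rule. It took Smarca5 and its paralog Smarca1, and then the 12 genes with the largest rise and the 12 with the largest fall past the threshold with 1 sign on all 4 arrays, without sex-linked genes and unnamed clones. If too few passed, it was filled with the genes of lowest p that had 1 sign on all 4 arrays and a fold of at least 1.5. It added the 4 members of lowest p in each called list, and En1, En2, Atoh1, Calb1, Pcp2, Gli1, Mycn, Ccnd1 and the linker histones H1f2 and H1f0. No gene measured here had the name Gli1 or H1f0. A few features listed under clone names are now assigned to named genes, and these were kept under the current name.

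The fit was tested on simulated data for the 21476 genes with shared RNA samples. Of 50 genes changed by a log2 ratio of 1, 0% were recovered. The recovered shares were 42% at a log2 ratio of 2, 56% at 3 and 86% at 4. Among unchanged genes, 5.55% had an unadjusted p under 0.05. Fitting those simulated arrays as independent gave 12.2%, and recovered 14% of the genes changed by a log2 ratio of 1. On simulated arrays with no correlation, the fit with a correlation of 0.5 recovered 0%, 26%, 54% and 78% at log2 ratios of 1, 2, 3 and 4, and 1.92% of unchanged genes had an unadjusted p under 0.05. Fitted as independent, simulated arrays with no correlation gave recovered shares of 0%, 60%, 78% and 100%, and 5.3% of unchanged genes had such a p. The correlation estimated from the real arrays was 4.2e-06. The simulated noise was taken from residuals of the fit with a correlation of 0.5, so it may differ from that of the real arrays. A shift of -0.25 in the granule cell progenitor list was called in 27 of 50 simulations and a shift of -0.5 in 50 of 50. Genes were simulated independently of each other, while the inter-gene correlation estimated for the real list was 0.0373, so these shares may not hold for it.

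The alternatives were arrays fitted as independent, a correlation between arrays estimated from the data, a dye term, no centring, equal spread between arrays, quantile normalization, turned dye-flip columns, robust variance moderation, each feature by itself, other thresholds, and leaving out each array in turn. Merging symbols with the same current name was added after the data were seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.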

Results

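The study compared the cerebella of newborn mice with a conditional knockout of Smarca5 (cKO) with those of wild-type mice, on 4 arrays that each carried RNA of both genotypes. There were 3 RNA samples per genotype. The comparison asks which genes differ in the newborn cerebellum when the Snf2h ATPase is deleted. All values are log2 ratios of cKO over wild type, a direction that is likely but not stated with the ratios, on a log base taken to be 2. Fitted values are given with their standard error (SE) over the 4 arrays.

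The targeted gene was examined first. The Smarca5 feature lay below 0 on every array, at -0.36, -1.16, -1.43 and -0.75 on replicates 1 to 4. The mean was -0.93 ± 0.47 (SD, n = 4 arrays from 3 RNA samples per genotype). The fitted ratio of Smarca5 was -0.98 ± 0.28 (SE), or 1.98-fold lower in cKO, with an unadjusted limma p of 0.0123 and an adjusted p of 1. With dye-flip columns turned the ratio was -0.21 (limma p 0.788). A feature annotated with a clone that is now a synonym of Smarca5 gave 0.23 ± 0.21 (SD, n = 4 arrays) and lay above 0 on all 4 arrays. With both features merged under Smarca5 the ratio was -0.42 (limma p 0.118). Smarca5-ps, annotated as a pseudogene of Smarca5, had ratios of -1.10, -1.59, -1.21 and -1.95 on replicates 1 to 4. Whether any of these features lies within the deleted part of the gene is not known here, so they check the labels only in part. The sign of the Smarca5 feature was used to choose the direction of the ratios, so it is no check of that direction. Smarca1, the gene of the other mouse ISWI ATPase, had a ratio of 0.00 ± 0.21 (SE, limma p 0.988). The measured members of ISWI complexes had a mean of -0.15 over 15 genes (camera adjusted p 0.286), which was -0.07 without replicate 3, and 35 genes of other chromatin remodellers had a mean of -0.04 (adjusted p 0.754).

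No single gene passed the test. Among 21476 genes, limma with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower, and the smallest adjusted p was 1. An unadjusted p under 0.05 was reached by 337 genes, of which 167 were higher and 170 lower in cKO, where evenly spread p-values would give 1074. On simulated independent arrays the same fit gave 1.92% of unchanged genes such a p. Fitted as independent arrays, limma called 0 genes as well, with 1061 genes at an unadjusted p under 0.05. Ratios had 1 sign on all 4 arrays in 2476 genes, or 11.5%, where chance gives 12.5% for independent arrays. Arrays correlated through shared RNA samples would give a larger share by chance. Between arrays the ratios correlated across genes only between -0.09 and 0.05 (Pearson; genes are not independent replicates). The simulated fit with a correlation of 0.5 recovered none of 50 genes at a log2 ratio of 1, so this fit would likely miss a change of that size in a single gene.

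With the columns as deposited, the highest ratios belonged to Rec8 and Zfp605, neither of which passed. Rec8, a cohesin subunit of meiotic chromosomes, had a ratio of 2.88 ± 0.30 (SE), or 7.36-fold, and lay between 2.45 and 3.36 on the 4 arrays (limma p 9.18e-05, adjusted p 1). Its adjusted p was 0.103 when the arrays were fitted as independent. Zfp605, a zinc finger gene, had a ratio of 3.36 ± 0.38 (SE), with values from 2.54 to 4.26 (limma p 0.000139, adjusted p 1). With dye-flip columns turned, Rec8 had 0.64 and Zfp605 1.17, and the gene of lowest p was Sec14l1 at 3.59 (adjusted p 0.373). The other 10 genes that the rule filled in on the higher side did not pass either. Among them the mitochondrial ribosomal protein gene Mrpl21 had a ratio of 1.68, the vomeronasal receptor gene Vmn1r217 1.44, the cytochrome P450 gene Cyp2c39 1.24 and Lce1a2 1.19. Cdkn3, a phosphatase that acts on cyclin-dependent kinases, had 1.14, the brain-expressed ADAR family gene Adarb2 1.09 and the protease gene Tmprss3 1.02. The ratios were 0.92 for B3galt6, whose 2 features gave 0.41 and 1.43, 0.90 for Clca1 and 0.79 for Fam24a. With symbols of the same current name merged, Clca1 had 0.23 (limma p 0.374).

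On the lower side, 3 of the 12 filled-in genes were beta protocadherins, which encode adhesion proteins of neurons from a gene cluster. Pcdhb17 had a ratio of -1.31 ± 0.28 (SE, limma p 0.00357), Pcdhb16 -1.22 ± 0.27 (SE, p 0.00437) and Pcdhb22 -1.07 ± 0.22 (SE, p 0.00333), each with an adjusted p of 1. With dye-flip columns turned these ratios were -0.05, -0.04 and -0.19. Hjurp, the chaperone that deposits the centromeric histone, had -1.43 ± 0.36 (SE, limma p 0.00735), and H3c3, a replication-dependent histone H3 gene, had -0.88. Smarca5-ps was among these genes, with a fitted ratio of -1.30 ± 0.34 (SE). The others were Olfr141 at -1.21, Cabp2 at -1.08, Vmn1r215 at -0.91, Fam47c at -0.91, Olfr495 at -0.87 and Slc35d2 at -0.82, which was -0.48 with merged names.

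**Figure D1:**
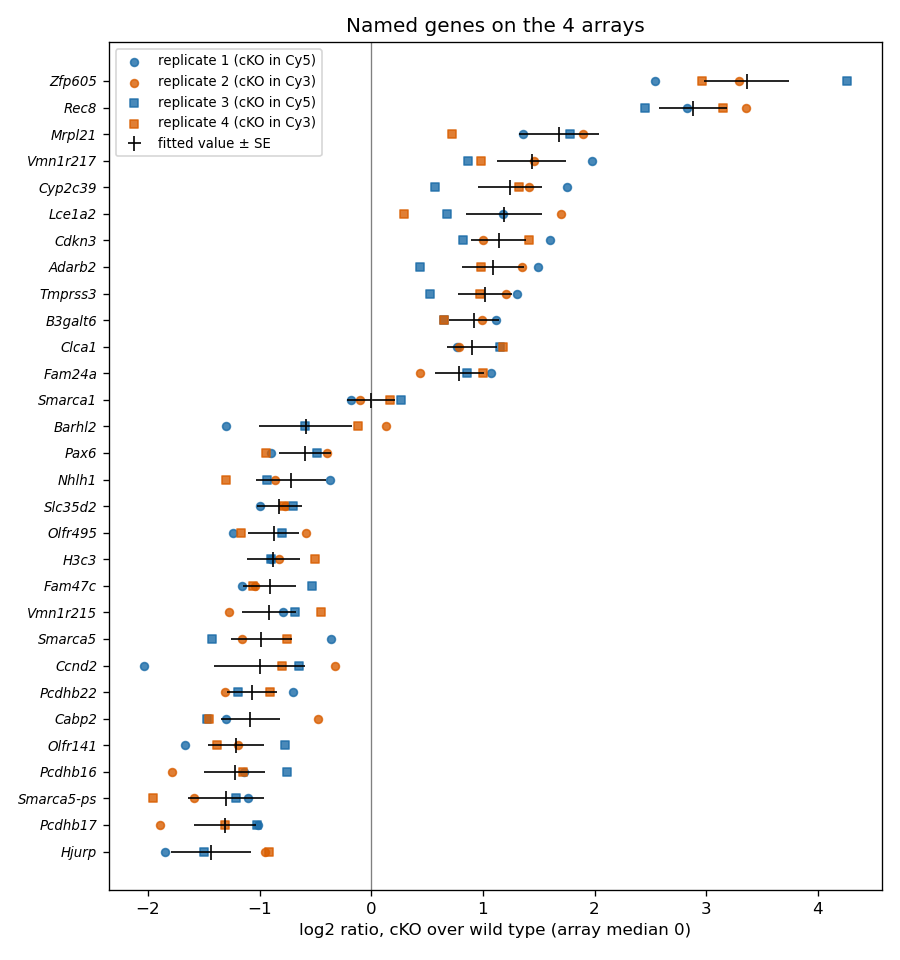
Log2 ratio of cKO over wild type (horizontal axis) for Smarca5, Smarca1, the filled-in genes and the named granule cell progenitor genes (vertical axis). Each of the 4 arrays has a point, blue for cKO in Cy5 and orange for cKO in Cy3, and a black bar gives the fitted value with its SE. The filled-in genes were chosen for 1 sign on all 4 arrays. Genes that the rule named in advance, such as En1 and Atoh1, are not drawn, apart from Smarca5 and Smarca1. Rec8 and Zfp605 lie above 2 on all arrays, and Smarca5 lies between -1.43 and -0.36.

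Granule cell progenitor genes were called lower as a group by camera at its preset correlation, but not by the tests run beside it. Their mean log2 ratio was -0.27 and their median -0.21 over 20 genes, of which 18 were below 0 and 4 were below 0 on all 4 arrays (camera p 6.57e-05, adjusted p 0.00204). This camera p sets the list against the other genes and does not measure the spread between RNA samples. With arrays fitted as independent, or with an estimated correlation between arrays, the call was kept (mean -0.29, camera adjusted p 0.000144). It was lost with an estimated inter-gene correlation, where the camera p was 0.0446 and the adjusted p 0.609. With fry, where the p was 0.0909 and the adjusted p 0.536, it was lost too. It was also lost with dye-flip columns turned (mean -0.20, camera adjusted p 0.332). No member passed over all genes tested (0) or adjusted over the list alone (0). The lowest p among members belonged to Pax6, a transcription factor of granule cell progenitors, with -0.59 ± 0.23 (SE, limma p 0.0428). The D-type cyclin gene Ccnd2 had -1.0 ± 0.41 (SE, limma p 0.0509), Nhlh1, a transcription factor gene of postmitotic neuronal precursors, -0.72 ± 0.31 (SE, p 0.0613) and Barhl2 -0.59 ± 0.42 (SE, p 0.211). Features of a gene differed, from -0.92 to -0.23 for Pax6 and at -0.62 and -1.38 for Ccnd2. Without replicate 1 the ratio was -0.55 for Ccnd2, which read -2.04 on that array, and -0.15 for Barhl2. The ratio of Barhl2 was -0.945 without replicate 2 and -0.35 without replicate 3. The list shared 3 genes with the Shh list and 1 with the DNA replication list. Its mean was -0.53, -0.10, -0.17 and -0.37 on replicates 1 to 4. On replicate 1, where this mean was lowest, Hoxb2 to Hoxb5, which mark the hindbrain behind the cerebellum, had a mean ratio of 3.14, against -0.18, -0.59 and -0.21 on the other arrays. Without replicate 1 the mean of the granule list was -0.20 and the call was lost (adjusted p 0.0525).

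Other lists tied to granule cells and proliferation did not pass. DNA replication and S phase genes had a mean of -0.13, with 37 of 45 genes below 0 and 9 below 0 on all 4 arrays (camera adjusted p 0.0568). This list did pass when the arrays were fitted as independent (adjusted p 0.000955). With arrays sharing RNA samples correlated, its adjusted p was 0.609 with an estimated inter-gene correlation and 0.536 with fry. The helicase subunit gene Mcm7 had -0.51 ± 0.26 (SE, limma p 0.0952) and the thymidylate synthase gene Tyms -0.49 ± 0.25 (SE, p 0.104), both below 0 on all arrays and named after their values were seen. Of the list's genes 0 had an unadjusted p under 0.05. Mitosis genes had a mean of -0.04 (56 genes, adjusted p 0.655). Shh pathway genes, which drive progenitor division, had -0.11 (14 genes, adjusted p 0.655), which was -0.000102 without replicate 1 and -0.23 without replicate 2. Differentiating granule neuron genes had a mean of -0.11 (21 genes, adjusted p 0.286). Among them Neurod1, named after its values were seen, had -0.95 ± 0.28 (SE, limma p 0.0151, adjusted p 1) and lay between -1.61 and -0.78. Ratios of progenitor regulators named in advance were small against their error, with Atoh1 at 0.17 ± 0.57, Mycn at -0.12 ± 0.22 and Ccnd1 at -0.34 ± 0.41 (SE). The ratio of Atoh1 was -0.26 with arrays fitted as independent. Leaving out 1 array moved Ccnd1 to -0.71 (without replicate 1) and -0.14 (without replicate 3), and Mycn to -0.02 (without replicate 2) and -0.24 (without replicate 3). The features of Ccnd1 ranged from -0.61 to -0.05.

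Purkinje cell genes had a mean of -0.03 over 22 genes (camera adjusted p 0.783), with Calb1 at 0.26 ± 0.32 and Pcp2 at 0.04 ± 0.34 (SE). Calb1 had 0.015 without replicate 2 and 0.56 without replicate 3, and its features gave 0.02 and 0.50. Engrailed and midbrain-hindbrain boundary genes had a mean of -0.04 (15 genes, adjusted p 0.754), with En1 at 0.03 ± 0.21 and En2 at 0.02 ± 0.29 (SE). Genes of GABAergic interneurons had a mean of -0.01 (16 genes, adjusted p 0.808). Those of cerebellar nuclei and unipolar brush cells had a mean of -0.07 and a median of 0.04 (10 genes, adjusted p 0.936). Genes of synapses and neuronal maturation had a mean of -0.09 (38 genes, adjusted p 0.527), and glial genes of the radial and astrocytic lineage 0.08 (26 genes, adjusted p 0.754).

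Microglia and macrophage genes had a mean of 0.14, with 14 of 21 genes above 0 and 5 above 0 on all 4 arrays (camera adjusted p 0.0688). This list passed with arrays fitted as independent (adjusted p 0.0212) and with each feature by itself (adjusted p 0.0386). It also passed without replicate 3 (mean 0.21, adjusted p 0.00734), while its mean was -0.005 with dye-flip columns turned. With arrays sharing RNA samples correlated, its adjusted p was 0.609 with an estimated inter-gene correlation and 0.554 with fry. Its member C1qb, a complement component named after its values were seen, had a ratio of 0.40 ± 0.20 (SE, limma p 0.0999). Means of other non-neuronal lists were 0.03 for choroid plexus (19 genes, adjusted p 0.983), -0.01 for meninges and fibroblasts (23 genes, adjusted p 0.983) and -0.06 for erythroid cells (11 genes, adjusted p 0.726). The choroid plexus mean was 0.11 without replicate 1, 2 or 3, and 0.14 with arrays fitted as independent. Endothelial cells and pericytes had a mean of 0.01, while camera placed the list slightly lower than other genes (20 genes, adjusted p 0.983). The oligodendrocyte list had a mean of 0.18 (13 genes, adjusted p 0.286) and the list of neighbouring midbrain and hindbrain 0.18 (21 genes, adjusted p 0.306). Both of these lay far above 0 on replicate 1 alone, and without it their means were -0.05 and -0.06.

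**Figure D2:**
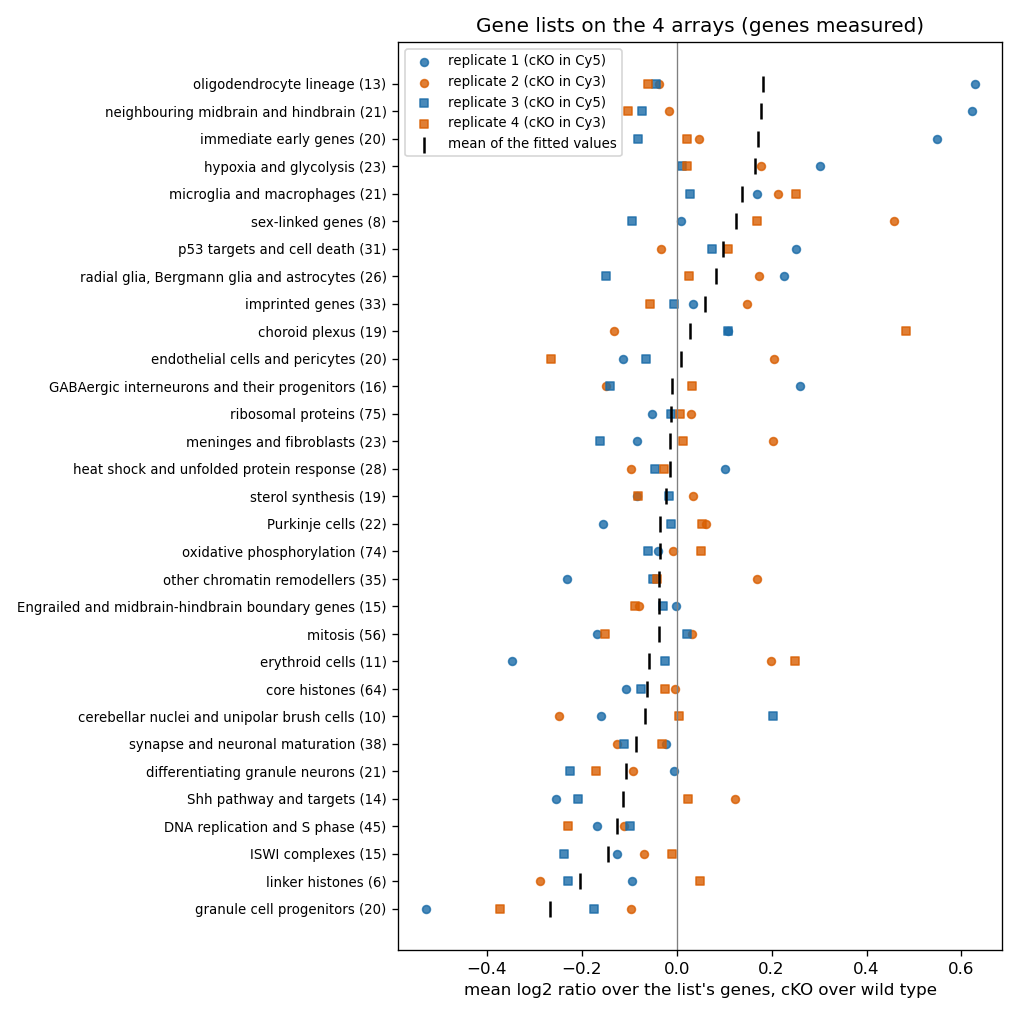
Mean log2 ratio of cKO over wild type (horizontal axis) of each gene list (vertical axis, number of genes in parentheses), with a point for each of the 4 arrays and a black bar for the mean of the fitted values. The granule cell progenitor list has the lowest mean, -0.27, and the oligodendrocyte and neighbouring midbrain and hindbrain lists stand above 0.6 on replicate 1.

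Chromatin and stress lists did not pass. Linker histone genes had a mean of -0.20 (6 genes, camera adjusted p 0.395), with H1f2 at 0.17 ± 0.30 (SE), and core histone genes had -0.06 (64 genes, adjusted p 0.287). Targets of p53 and cell death genes had a mean of 0.10, with 22 of 31 above 0 (adjusted p 0.238), and a mean of 0.04 without replicate 1 and 0.16 without replicate 2. Immediate early genes had a mean of 0.17 (20 genes, adjusted p 0.234), which was 0.55 on replicate 1 and between -0.08 and 0.05 on the others. Hypoxia and glycolysis genes had 0.16 (23 genes, adjusted p 0.238), and 0.09 without replicate 1. Heat shock and unfolded protein response genes had -0.01 (28 genes, adjusted p 0.808), sterol synthesis genes -0.02 (19 genes, adjusted p 0.712), ribosomal protein genes -0.01 (75 genes, adjusted p 0.808) and oxidative phosphorylation genes -0.04 (74 genes, adjusted p 0.535). Imprinted genes had a mean of 0.06 (33 genes, adjusted p 0.654) and sex-linked genes 0.12 (8 genes, adjusted p 0.655).

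The clustered protocadherins were set side by side after the values of the 3 named members had been seen. The 22 beta genes had a mean ratio of -0.71, with 21 below 0 and 14 below 0 on all 4 arrays. Their means were -0.69, -0.82, -0.62 and -0.70 on replicates 1 to 4. The 14 alpha genes, of which 13 were below 0, had a mean of -0.24, which was -0.14 without replicate 1 and -0.16 without replicate 3. The 22 gamma genes, of which 12 were below 0, had -0.04, a mean whose sign differed between settings. Members of a cluster are alike in sequence.

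**Figure D3:**
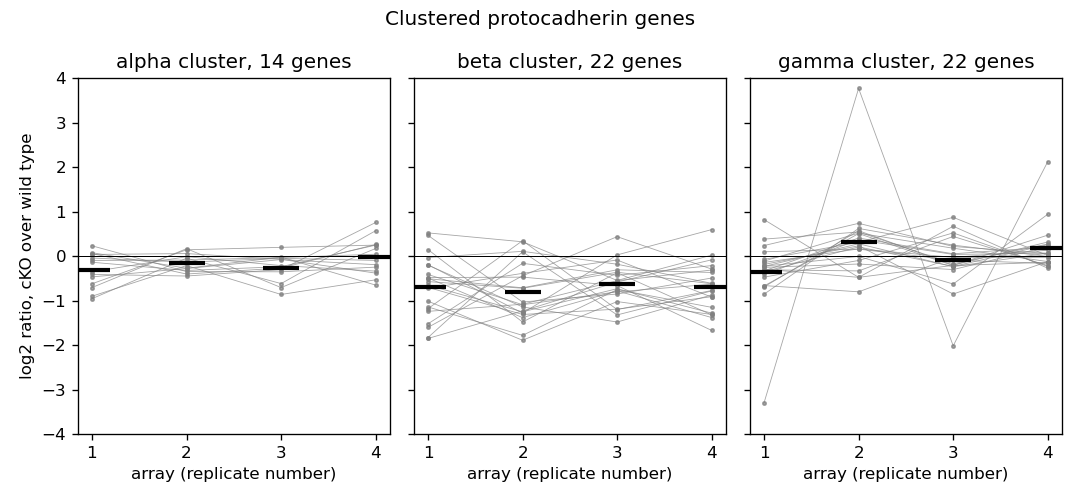
Log2 ratio of cKO over wild type (vertical axis) on each array (horizontal axis) for alpha, beta and gamma protocadherin genes, with a grey line per gene and a black bar for the mean of the genes on that array. The beta means lie between -0.82 and -0.62 on the 4 arrays.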

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

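Of the tests in this part, the comparison of wild-type samples and the test of wider noise were chosen after the values were seen. On replicate 1 the oligodendrocyte list had a mean log2 ratio of 0.63, while the other 3 arrays lay between -0.06 and -0.04. The list of neighbouring midbrain and hindbrain genes had a mean of 0.62 on replicate 1, against -0.10 to -0.02 on the others. Both stood out because the gap between replicate 1 and the nearest array was most of the range of the 4 arrays. Of 69 values examined in this way 2 stood out, and chance would give 3.45.

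The high hindbrain list on replicate 1 came from its Hox genes, because its other 14 genes had a mean of -0.09 there. The 15 Hox genes of the anterior and middle groups outside the list had a median of 1.24 on replicate 1 (percentile 100 among 10000 random lists), and a list of 23 spinal cord and caudal medulla genes had a mean of 0.56 (percentile 100). Of these 15 were above 0 and 8 below, from the glycine transporter gene Slc6a5 (also in the interneuron list) at 3.92 to Tlx3 at -1.11 and Pou4f1 at -1.44, and without Slc6a5 the mean was 0.41 (percentile 99.7). Hindbrain tissue missing from the wild-type sample is argued against by replicate 4, which used the same wild-type sample and had a mean of -0.21 for Hoxb2 to Hoxb5, and wider noise by the 15 other Hox genes, at percentile 100 of lists from the same array. A candidate explanation is some caudal hindbrain or spinal cord tissue in the cKO RNA of replicate 1, a sample used on that array alone, while cerebellar cells with more caudal Hox expression stay open and were not tested.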

How the results depend on the processing

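The count of called genes was 0 under every setting run, including an adjusted p under 0.1. Genes at an unadjusted p under 0.05 numbered 337, and 1061 with independent arrays or an estimated correlation between arrays (which came out near 0, at 4.2e-06), 661 with a dye term, 146 without replicate 2 and 995 without replicate 4. The Smarca5 ratio of -0.98 stayed below 0 in every setting, though a feature now assigned to Smarca5 lay above 0 on all 4 arrays. That ratio became -0.21 with dye-flip columns turned and -0.42 with merged names, and was -1.12 to -0.81 when an array was left out. In the estimate, turning the columns changes the sign of replicate 2 alone, so a ratio below 0 in that setting says little. The number of called lists was 1. It was 3 with independent arrays, with an estimated correlation between arrays and with each feature by itself, and 2 with a dye term. It was 0 with dye-flip columns turned, with camera at an estimated inter-gene correlation and with fry. Leaving out an array gave 1 to 3, with 3 without replicate 3. Without replicate 1 the 1 called list was DNA replication (adjusted p 0.0449). The granule progenitor mean of -0.27 was called no more with turned columns (-0.20, adjusted p 0.332), an estimated inter-gene correlation (-0.27, adjusted p 0.609) or fry (-0.27, adjusted p 0.536). Leaving out an array gave -0.35 to -0.20, and the call ended without replicate 1 (adjusted p 0.0525). Independent arrays without replicate 1, chosen after seeing the data, gave -0.21 (adjusted p 0.0295). Apart from Smarca5 and the granule list, 470 values for named genes and 370 for lists kept their direction and side of the threshold, 26 and 40 changed sign without being called, and 10 of the DNA replication and microglia lists became called. For genes this says little, since none was called under any setting. The counts also hold settings that could change little. Robust moderation left the list tests as they were, and an estimated correlation near 0 between arrays repeated the fit with independent arrays. Leaving out replicate 4, whose weight in the estimate is 0, could change no direction. With turned columns all 24 filled-in genes, which were chosen for 1 sign on the columns as deposited, had smaller ratios (median size 0.32 against 1.12), and 0 had an unadjusted p under 0.05. With turned columns, which would make the ratios a contrast of dyes, the sign changed for Mycn (0.0933), Atoh1 (-0.233), Calb1 (-0.24), En1 (-0.107), Pcp2 (-0.477) and Smarca1 (0.0633). It also changed for the Engrailed (0.0161), GABAergic (0.089), cerebellar nuclei (0.0972), endothelial (-0.128), heat shock (0.05), imprinted (-0.0396), microglia (-0.005), radial glia (-0.0323) and sex-linked (-0.182) lists. With independent arrays, and with an estimated correlation between arrays, it changed for Atoh1 (-0.263), En2 (-0.08), Smarca1 (0.04) and the GABAergic (0.000495), endothelial (-0.0601) and erythroid (0.0192) lists. The dye term changed it for En2 (-0.0375), Smarca1 (0.00625) and the endothelial (-0.00127), erythroid (0.0128) and meningeal (0.0171) lists. Each feature by itself changed it for the choroid plexus (-0.0259), imprinted (-0.0105) and radial glia (-0.00572) lists. Smarca1 became 0.0127 with equal spread, 0.00333 without centring and 0.0125 with quantile normalization, which also turned the GABAergic list (0.0118). Leaving out an array moved Smarca1 from -0.0457 to 0.0829, En1 from -0.06 to 0.134, En2 from -0.236 to 0.06, Atoh1 from -0.244 to 0.173, Pcp2 from -0.325 to 0.314 and H1f2 from -0.0557 to 0.327. Among lists the range was -0.0836 to 0.0388 for Purkinje cells, -0.0949 to 0.0593 for GABAergic interneurons, -0.15 to 0.0222 for cerebellar nuclei, -0.122 to 0.0675 for meninges, -0.0896 to 0.0085 for endothelial cells and -0.185 to 0.149 for erythroid cells. It was -0.0459 to 0.292 for oligodendrocytes and -0.0579 to 0.275 for neighbouring midbrain and hindbrain, both lowest without replicate 1. For other remodellers it was -0.14 to 0.0467, for heat shock -0.0619 to 0.0271, for ribosomal proteins -0.0323 to 0.0113, for oxidative phosphorylation -0.0495 to 0.000247 and for sex-linked genes -0.0434 to 0.247. The causes of these changes were not tested. No value was missing, so the rule for missing values changed nothing, and the filter on dim features was not run. Signal over background was not analysed here. Both genotypes are on each array, so every ratio is already a comparison within an array, and no further pairing was used.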

Other observations

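Tests chosen after the results were seen were those of dye, of the shift over all clusters and of replicate 1 for protocadherins, those of dye, of other cell types, of the mean over genes without replicate 1 and of independent arrays without it for granule genes, and the sign count for called genes. The lower beta protocadherins were also found in the data, and were then set against 251 gene families of 10 or more genes formed from symbol stems. The beta family alone passed with camera at its preset correlation (p 1.14e-19, adjusted p 2.86e-17, mean -0.71). That p counts genes alike in sequence as nearly independent and does not measure the spread between RNA samples. With an estimated inter-gene correlation the family's camera p was 0.00363 and its adjusted p 0.91. With fry they were 0.00224 and 0.563, so the family passed in neither of these tests. Its mean stayed between -0.75 and -0.66 when any array was left out, and was -0.70 with no centring, -0.72 with equal spread and -0.70 with quantile normalization. It was -0.17 with turned dye-flip columns. Of its genes 10 had an unadjusted p under 0.05 and 3 passed adjusted over the list alone. Those 3 were the named members whose values had prompted the list, so they add no support. The alpha genes had a camera p of 0.00134. The alpha family formed from the stem, with 12 genes, did not pass (camera adjusted p 0.238, 0.997 with an estimated inter-gene correlation, 0.998 with fry). The alpha p was 0.0296 without replicate 1, 0.0245 without replicate 3 and 0.129 with turned columns. The gamma genes had a mean of -0.04 (camera p 0.896). Their mean was -0.26 with turned columns (p 0.00144) and -0.23 without replicate 2 (p 0.122). It was above 0 without replicate 1 (0.16), without replicate 3 (0.08), with independent arrays (0.01) and with a dye term (0.03).

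A dye bias of these genes is argued against by means of -0.66 ± 0.09 with cKO in Cy5 and -0.76 ± 0.10 with cKO in Cy3 (SE over genes). The difference between beta and the other clustered protocadherins was -0.59 (permutation p 1e-05, the smallest the resamples can give). That p is no separate support, because the beta genes were singled out in these data and members alike in sequence were shuffled as if independent. With 13 of 14 alpha genes also below 0, a shift of all clusters that differs in size stays open. Tissue in replicate 1 is argued against by a mean of -0.73 without it, with 22 of 22 beta genes below 0. Cross-hybridisation that gives the members 1 common ratio cannot be told apart from separate changes, because the variance between genes was not clearly above chance (F 1.48, permutation p 0.112), a p first meant to count for it and read as open after it was seen. Of 8 sign patterns of the arrays, 1 gave a camera p as small as the real one, at 1.14e-19 against 1.55e-08 for the next. This is no support, because the named members were chosen for 1 sign on the columns as deposited, which favoured the real pattern in advance. The next pattern turned replicate 4 alone, which has a weight of 0 in the estimate, and 8 are too few for a share under 0.05. Lower expression of the beta cluster in cKO is a hypothesis that stays open, and few transcripts shared by many probes may be behind it.

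For the granule progenitor list, the means were -0.35 ± 0.08 with cKO in Cy5 and -0.23 ± 0.11 with cKO in Cy3 (SE over genes). Means below 0 in both dye orientations argue against a dye bias on these arrays. An SE over genes does not measure the spread between RNA samples. Without replicate 1 the mean went from -0.27 ± 0.06 to -0.20 ± 0.09 (SE over genes), with 16 of 20 genes below 0. Replicates 2 to 4 had list means of -0.10, -0.17 and -0.37. The camera call ended without replicate 1 (adjusted p 0.0525), and why was not tested. Arrays fitted as independent without replicate 1 gave -0.21 (adjusted p 0.0295). Whether caudal tissue in replicate 1 was the whole cause cannot be decided from these values. A larger share of all other cell types cannot be told apart from fewer granule cell progenitors or lower expression in them, because 6 of 11 lists of other cell types had a mean above 0 and none lay below 0 by more than its error. Of the 8 sign patterns 1 gave a camera p as small as the real 6.57e-05, and 8 are too few for a share under 0.05. The next, with a camera p of 0.00308, turned replicate 4 alone, which has a weight of 0 in the estimate.

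For single genes the 8 patterns are also too few. All 8 gave 0 called genes, the real value being 0 and the highest other 0. At an unadjusted p under 0.05, 3 of the 8 gave as many genes as the real 337. The highest other, 419, set replicates 1 and 4, which share a wild-type sample, against replicates 2 and 3, and the pattern that follows the dyes gave 362.

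The high ratio of Rec8 led to the hypothesis that germline genes are higher in cKO as a group. A list of 28 germline genes without Rec8, fixed before it was tested, had a mean of -0.00464 ± 0.08 (SE over genes, camera p 0.942). Of these genes 10 were above 0, and 5 were above 0 on all 4 arrays, against 1269 of all 21476 genes. The mean plus 2 SE was 0.15, so a shift of 0.25 shared by the whole list is argued against on these arrays. This SE does not measure the spread between RNA samples, and a rise of some members stays open. Among 8375 features without a gene symbol limma called 0, with 90 at an unadjusted p under 0.05.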
